A study of Mus musculus with 5 samples.

How the data were processed

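Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used on mouse B cells of the C57BL/6 strain. The antibody was against IRF4 (code M-17) or IRF8 (code C-19). The 5 libraries formed 5 groups of 1 library each, as the sample titles give them: IRF4 and IRF8 after 48 h and after 72 h of culture with lipopolysaccharide (LPS), and IRF8 in germinal centre (GC) B cells taken directly from immunised mice. Each header of the 4 LPS lists names 1 set of tags, per the file headers, and that of the IRF8 72 h list marks its tags as a second replicate. Whether that list rests on a second or a merged library, which bears on every IRF8 72 h value, and whether reads were pooled for the GC list are not given in the sources used here. No input or other control library was named in the headers of the LPS lists, and none was analysed here.

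The 4 LPS lists were made by the authors with findPeaks of HOMER in its transcription factor mode, per the file headers. Those headers state peaks of 500 bp centred on the highest pile-up of tags, a minimum distance of 1000 bp between peaks, at most 1 tag per position, a false discovery rate of 0.001, a fold of at least 4 over the surrounding 10000 bp and a Poisson p-value of at most 1e-04 against that region. The GC list held intervals with a chromosome, a start and an end, with no score, summit or signal; it was called with MACS per the design text of the series, whose version, threshold and control are not given in the sources used here. Caller and cell type are thus confounded in every comparison of the GC list with an LPS list, and the GC cells were also frozen and processed by a service company, per that text. The submitters' processing notes name BWA and Bowtie2 without a version, while the design text gives other words for the alignment step, so which program aligned which library is not settled. The build was mm9 per the labels; all placed intervals lay inside the mm9 chromosomes.

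In the deposited LPS lists, the signal of a peak is its normalised tag count, scaled by the authors to 10000000 tags per library, per the file headers. The findPeaks score is, per the file headers, the number of tags in the peak after the limit on tags per position. The fold over the local region and the fold against the tag positions that clonal reads would leave are ratios given by the authors' caller, and the p-value of each peak is the authors' Poisson value against the local region. The focus ratio is a fraction given by the authors' caller, the share of tags in their proper place around the peak centre. The deposited GC list gives positions in BED format and no other unit. The tag count of a peak is the authors' own value and served to rank peaks within a list. Tag counts of LPS libraries were also set side by side, because all 4 headers state the same scaling; such a comparison is one of libraries, not of culture conditions, and the share of tags that fell in peaks differed between them. The deposited score, folds, p-values and focus ratios were not used in a test.

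Peaks were ranked by normalised tag count. Dividing out the scaling gave whole tag numbers within 0.05 for 100% of the peaks of each LPS list, and these tag numbers gave the exact Poisson intervals of single peaks and the exact binomial tests between 2 libraries. Intervals for shares are exact Clopper-Pearson intervals at 95%. All intervals cover counting error only, since sequenced tags without molecular identifiers are not independent molecules and no group had a second library. Peaks on sequences that the reference genome did not hold as placed chromosomes had no position for annotation or motifs (9, 12, 8, 11 and 0 peaks in the IRF4 48 h, IRF4 72 h, IRF8 48 h, IRF8 72 h and GC lists); they stayed in the counts and overlaps. The mitochondrial chromosome was kept as a placed sequence.

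Genes were annotated with GENCODE M1 on the NCBIM37 assembly, which is mm9. A peak was a promoter peak when its centre lay within 1000 bp of a transcription start site (TSS), and it was assigned to the protein-coding gene with the nearest TSS, within 50000 bp for the gene lists. To find repeated sequence, all words of 24 bases within 100 bp of a peak centre were counted in the whole genome on both strands, and a peak was called multi-copy when the median word was found more than 1 time. Motifs were searched on both strands within 100 bp of the peak centre: the composite ETS-IRF element (EICE, GGAANNGAAA), the composite AP-1-IRF elements (AICE1, GAAATGASTCA, and AICE2, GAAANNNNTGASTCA), the core of the interferon-stimulated response element (ISRE, GAAANNGAAA), a PU.1-type ETS site (AGAGGAAGTG) and the AP-1 site (TGASTCA). Windows whose sequence was not complete were left out.

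Shared peaks were those that overlapped by at least 1 bp, counted in the shorter list and compared with 1000 random placements of that list on the same chromosomes (one-sided permutation test, smallest possible p 0.001, over 10 pairs of lists). Random placement ignores open chromatin and is a low bar. Whether peaks of a list lay more often in one list than in another was tested with the exact McNemar test, two-sided, after both lists were reduced to the same number of their highest peaks (18 tests). The GC list has no ranking and was used whole. Tag counts of shared and unshared peaks were compared within a list with a two-sided permutation test of rank sums (100000 permutations). Motif shares were compared with windows 1000 bp to each side of the same peaks by an exact permutation of peak and flank, two-sided (30 tests), and between lists by Fisher's exact test, two-sided (60 tests). Promoter shares were compared by Fisher's exact test, two-sided. Each of 12 gene lists was tested in each peak list by Fisher's exact test, one-sided, against all other of 22238 protein-coding genes; 274 of 283 list entries matched the annotation. All p-values were adjusted by the Benjamini-Hochberg method within these families, and 0.05 was the threshold. Whether a motif share changed differently in time for IRF4 and IRF8 was tested by a permutation of the antibody within each culture time.

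The gene lists were plasma cell, germinal centre, B cell identity and receptor signalling, antigen presentation, interferon response, Toll-like receptor and NF-kappaB signalling, the AP-1 and BATF family, cell cycle and apoptosis, immunoglobulin and class switch, myeloid and dendritic cells, T cells, and housekeeping. The design, the gene lists, the motifs, the alternative settings and the rule for named genes were fixed before the data were examined. The rule named the 5 peaks with the most tags in each list, the 10 shared peaks with the lowest sum of ranks and the 5 highest unshared peaks of each pair of interest, every member of a gene list with a peak in 3 or more lists, and 12 genes in any case, among them Irf4, Irf8, Prdm1, Bcl6, Bach2, Pax5, Spib, Ciita, Xbp1, Zbtb20 and Ebf1. Some of the genes covered by the lists and the rule are not reported here. Because the highest peaks turned out to be multi-copy, the same ranking among single-copy peaks was added after the values were seen.

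The alternatives were a larger minimum overlap, peak centres within 100 or 1000 bp, the top part of each ranked list, lists of equal length, random shifts of 10000 to 100000 bp, a promoter of 2500 bp, gene assignment within 10000 bp or to every TSS within 50000 bp, motif windows of 50 bp, flanks 5000 bp away, and autosomes and X with overlapping peaks merged. Added after the data were seen were single-copy peaks only, the whole interval as motif window, all these motif settings for differences between lists, autosomes and X for motifs and promoters, an exact binomial test over peaks for the gene lists, and lists of equal length for the change of motifs in time.

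The tests were tried on simulated data. Overlaps of unrelated lists passed 0.05 in 2% of 100 runs. The motif test with nothing planted passed in 2%, 2.5%, 7% and 4% of runs for lists of 234, 898, 1573 and 1826 peaks, and with a motif planted in 5% of peaks it passed in 75.5%, 99.5%, 100% and 100%. For the IRF4 48 h list size of 1573 peaks, the gene list test called a list with 8 of 25 planted members in 100% of runs and made a false call in 2%. Those runs used random positions and random genes, so they do not cover peaks that follow open chromatin. The gene list test ignores open chromatin and is a low bar too. Python 3.11.15 was used with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and pysam 0.24.0, and figures were drawn with matplotlib 3.10.9.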

Results

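IRF4 and IRF8 are related transcription factors of the interferon regulatory factor family, and the series set their binding sites in mouse B cells side by side. Naive B cells from the spleen were activated in culture with LPS, a bacterial cell wall component that acts through Toll-like receptors, and ChIP-seq was done for each factor after 48 h and after 72 h. IRF8 was also mapped in GC B cells, the dividing cells of the germinal centre in which antibody genes mutate, taken from mice immunised with a hapten-protein conjugate. Each of the 5 groups held 1 library, so no difference between groups has a replicate check, and every p-value describes these libraries and lists, not the conditions. The IRF4 lists held 1573 peaks at 48 h and 898 at 72 h, the IRF8 lists 234 peaks at 48 h and 1059 at 72 h, and the GC list 1826 intervals. The LPS libraries held 3396941, 3766015, 4375858 and 3065426 tags in that order (IRF4 48 h, IRF4 72 h, IRF8 48 h, IRF8 72 h). Of these tags, 0.82%, 0.45%, 0.18% and 0.52% fell in peaks, per the file headers. The depth of the GC library is unknown, since its list gives positions alone.

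The number of peaks went in opposite directions in time for the 2 factors: the IRF4 list was longer at 48 h and the IRF8 list longer at 72 h. The IRF8 48 h library had the most tags and the fewest peaks, so depth alone did not set the order. Peak numbers depend on the threshold of the caller. With a common minimum of 32.6 normalised tags, the median of the 4 pooled LPS lists, 969 IRF4 peaks remained at 48 h and 350 at 72 h, against 79 and 576 IRF8 peaks. The places with the most tags were the same in the 4 LPS lists. The highest peak of each, at chromosome 2, 98507043 to 98507543 of mm9 in the IRF4 48 h list, next to the predicted gene Gm10800, carried 4651 normalised tags, with 4684, 3631 and 4711 in the other LPS lists. Of the 20 highest peaks, 80% to 85% lay in multi-copy or unplaced sequence in each LPS list, and these 20 peaks held 17.9%, 31.6%, 62.5% and 28.7% of all tags in peaks. Multi-copy peaks were 4.48% and 6.09% of the placed IRF4 peaks at 48 h and 72 h, 21.7% and 12.6% of the IRF8 peaks, and 7.72% of the GC peaks.

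Where the peaks lay relative to genes was asked first. In the GC list 26.4% of IRF8 peaks were promoter peaks (482 of 1826, 95% interval 24.4 to 28.5), against 9.83% of IRF8 peaks at 72 h (8.09 to 11.8) and 10.2% at 48 h (6.56 to 14.9). IRF4 peaks were at promoters in 9.21% of cases at 48 h (7.82 to 10.7) and 14.9% at 72 h (12.6 to 17.4). Most other peaks were intronic or intergenic: introns held 44.6% of IRF4 48 h peaks, 40.4% of IRF4 72 h peaks, 38.5% and 40.3% of IRF8 peaks at 48 h and 72 h, and 34.5% of GC peaks. The GC share was above each LPS share (Fisher's exact test, two-sided, adjusted p between 1.24e-38 and 2.72e-08). IRF4 promoter peaks were a larger share at 72 h than at 48 h (Fisher's exact test, odds ratio 0.579 for 48 h over 72 h, adjusted p = 5.25e-05). In the top part of the ranked lists the gap was smaller and the intervals overlapped, with no test. The shares there were 7.95% at 48 h (6.15 to 10.1) and 11.1% at 72 h (8.33 to 14.4). With a promoter of 2500 bp the shares were 16.6%, 23.1%, 16.4%, 17.6% and 34.4% in the order of the lists above. The GC list was called by another program on intervals with a median width of 1144.5 bp against 500 bp, so the cell type and the caller are not separable in this comparison.

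The first comparison asked how IRF4 binding moved from 48 h to 72 h of LPS culture, the period in which some activated B cells become plasmablasts. AP-1 sites, bound by JUN, FOS and BATF family proteins, lay under 28.7% of IRF4 peaks at 48 h (95% interval 26.5 to 31.1) and 18.5% at 72 h (16.0 to 21.2). The EICE, bound by IRF4 or IRF8 together with the ETS factors PU.1 or SPIB, went the other way, from 14.7% (12.9 to 16.5) to 25.6% (22.8 to 28.6). AICE1, where IRF4 binds together with AP-1 proteins, was under 3.65% of peaks at 48 h and 2.03% at 72 h, and the ISRE under 4.55% and 7.11%. The AICE1 consensus contains that of AP-1, so each AICE1 peak is also an AP-1 peak and not a separate result. Peaks found at 48 h alone held an AP-1 site in 31.4% and an EICE in 9.01% of cases, while peaks found at 72 h alone held them in 11.5% and 24.7%. At the 536 places bound at both times, tags fell most where an AP-1 site was the only element of the pair: the median log2 ratio of 72 h over 48 h was -0.69 at 116 AP-1 peaks, -0.27 at 127 EICE peaks and -0.30 at 278 peaks with neither. Of the other places, 9 held both and 6 had no complete motif window.

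The differences in motif share passed Fisher's exact test, two-sided, with odds ratios for 48 h over 72 h of 1.78 for AP-1 (adjusted p = 5.86e-08), 0.499 for the EICE (adjusted p = 2.69e-10), 1.83 for AICE1 (adjusted p = 0.0499) and 0.622 for the ISRE (adjusted p = 0.0205). Each of AP-1 and EICE stood above the flanking windows at both times; the flanks held AP-1 in 4.71% and 4.35% and the EICE in 2.05% and 1.86% of cases. Tags were lower at 72 h at 108 of 116 AP-1 peaks and 87 of 127 EICE peaks, and the ratios of these classes differed (permutation test, two-sided, p = 1e-05, the smallest 100000 permutations can give). The ISRE share of the IRF4 48 h list was 3.14% in the flanks (exact permutation of peak and flank, adjusted p = 0.0312). That call ended with flanks 5000 bp away, with windows of 50 bp and in the top part of the list (exact permutation, adjusted p = 0.0886 to 0.347). Over whole intervals the differences between the times no longer passed for the ISRE (Fisher's exact test, adjusted p = 0.384) and AICE1 (adjusted p = 0.101). In the top part of the lists they did not pass either (Fisher's exact test, adjusted p = 0.646 and 0.608), while AP-1 and the EICE did.

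**Figure D1:**
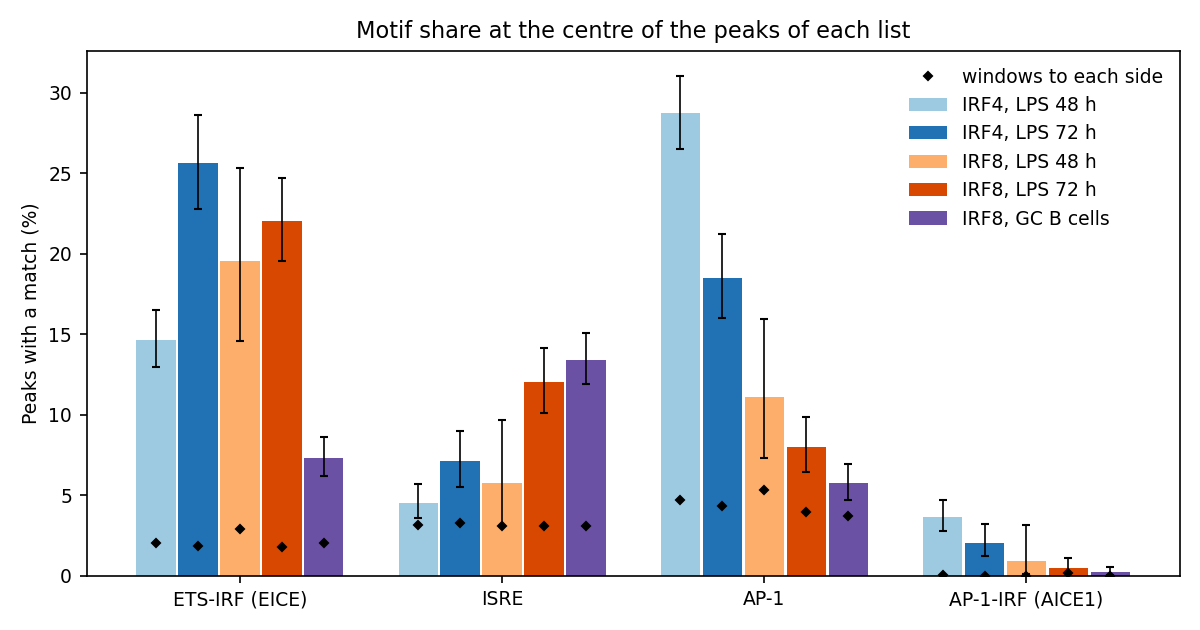
Share of peaks (%, y axis) with a match to the EICE, ISRE, AP-1 or AICE1 consensus within 100 bp of the peak centre, for the 5 lists (bars, with exact 95% intervals) and for windows 1000 bp to each side (diamonds). The AP-1 bar falls from 28.7% to 18.5% between the IRF4 lists while the EICE bar goes from 14.7% to 25.6%, and the GC list has the lowest EICE bar, 7.34%.

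IRF4 peaks at 48 h and 72 h overlapped at 536 places, 59.7% of the shorter 72 h list. Random placements, with unplaced peaks left in place, gave 0.733% (permutation test, one-sided, adjusted p = 0.001, the smallest it can give). Random placement is a low bar. With single-copy peaks, which leave out unplaced sequence, the observed and random shares were 58.8% and 0.0613%. Shared peaks were the higher ones, with a median of 47.1 normalised tags against 35.3 for unshared peaks at 48 h. Among single-copy peaks, a choice made after the values were seen, a pair of peaks led the IRF4 48 h list with 247.3 normalised tags each (95% Poisson interval 197 to 306). A peak with an AP-1 site 8.54 kb upstream of Grap, which encodes an adaptor protein of lymphocyte receptor signalling (chromosome 11, 61457977 to 61458477, intergenic), carried 85.0 tags at 72 h (58.1 to 120). The other peak, in an intron of Cdk8, carried 191.2 (150 to 241). A peak 45.4 kb upstream of Enpp6 with AICE1 carried 185.5 tags at 48 h (143 to 237) and 111.5 at 72 h (80.4 to 151). The Cdk8 peak and peaks near Axin2 and Pak3 were among the 5 highest single-copy IRF4 peaks at both times, held none of the 6 motifs and were found in all 4 LPS lists.

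**Figure D2:**
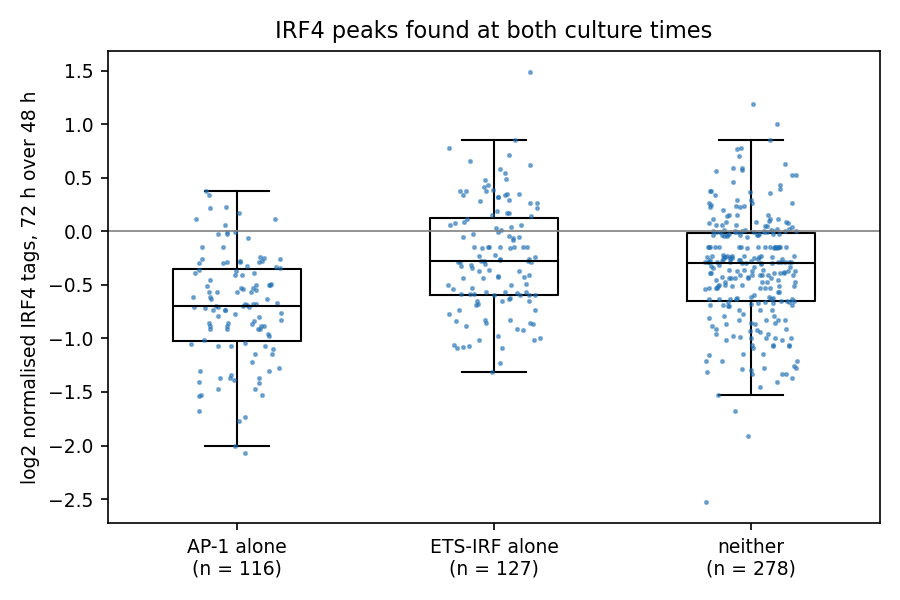
log2 ratio of normalised IRF4 tags at 72 h over 48 h (y axis) at peaks found at both times, for peaks with an AP-1 site alone (n = 116), an EICE alone (n = 127) or neither (n = 278). Each point is a peak, boxes span the quartiles with the median as a line, whiskers reach 1.5 times the box, and the medians are -0.69, -0.27 and -0.30.

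The second comparison set IRF4 against IRF8 at the same culture time, the contrast of the 2 factors that the series title describes as antagonists. AP-1 sites set them apart at both times: at 48 h they lay under 28.7% of IRF4 peaks and 11.1% of IRF8 peaks (7.32 to 16.0), and at 72 h under 18.5% and 8.02% (6.44 to 9.83). At 72 h the ISRE, the element of interferon-induced genes, lay under 12% of IRF8 peaks (10.1 to 14.1) and 7.11% of IRF4 peaks. The EICE lay under 14.7% of IRF4 and 19.6% of IRF8 peaks at 48 h, and 25.6% and 22.0% at 72 h. Among single-copy peaks the shares were 15.2% (13.4 to 17.1) and 25% (18.8 to 32.1) at 48 h, and 27.3% and 24.5% at 72 h. The places bound by both at 72 h held the EICE in 34.9% of 249 windows at the IRF4 centres and 35.3% at the IRF8 centres. IRF4 peaks alone held it in 22.0% and IRF8 peaks alone in 17.9%. The shared places were not tested against the others and had more tags. Their medians at 72 h were 39.8 against 29.2 for IRF4 and 39.1 against 29.4 for IRF8. In the top part of the 72 h lists the EICE share was also higher, 30.6% for IRF4 and 28.3% for IRF8. Peaks of IRF4 alone at 72 h had AP-1 in 20.1% and the ISRE in 6.12%, and peaks of IRF8 alone had them in 6.26% and 12.6%.

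By Fisher's exact test, two-sided, AP-1 differed at 48 h (odds ratio IRF4 over IRF8 3.23, adjusted p = 1.19e-08) and at 72 h (2.61, adjusted p = 4.77e-11), and the ISRE at 72 h (0.560, adjusted p = 9.16e-04). The EICE did not pass the Fisher test at 48 h over all peaks (adjusted p = 0.103) or in the top part of the lists (adjusted p = 0.944). It passed at 48 h with single-copy peaks, added after the data were seen (Fisher's exact test, odds ratio 0.538, adjusted p = 0.00496), and with windows of 50 bp (adjusted p = 0.0122). At 72 h the Fisher test gave an adjusted p of 0.110 (0.0330 over whole intervals) for the EICE, and at 48 h 0.458 for the ISRE. AICE1, whose peaks are all AP-1 peaks too, was under 0.889% of IRF8 peaks at 48 h and 0.477% at 72 h. Its share was below that of IRF4 at 48 h (Fisher's exact test, adjusted p = 0.0499) and 72 h (adjusted p = 0.00653). These calls ended in the top part of the lists (Fisher's exact test, adjusted p = 0.233 and 0.0513), and that at 72 h with windows of 50 bp (adjusted p = 0.132).

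IRF4 and IRF8 shared 122 places at 48 h, 52.1% of the IRF8 list, and 258 at 72 h, 28.7% of the IRF4 list. Random placements, with unplaced peaks left in place, gave 2.20% and 1.05% (permutation test, one-sided, adjusted p = 0.001 for both, the smallest possible). With single-copy peaks, which leave out unplaced sequence, 50.3% and 25.2% were shared, against random shares of 0.0655% and 0.0371%. These shares are of the shorter list, IRF8 at 48 h and IRF4 at 72 h, so they do not compare the 2 times. Cut to the 234 highest peaks of each list, IRF4 and IRF8 shared 23.1% at 48 h and 39.7% at 72 h, the opposite order, with no test between the times. With lists of equal length, IRF4 48 h peaks lay more often in the IRF4 72 h list (34.1%) than in the IRF8 72 h list (17.0%; 351 peaks in the former alone and 82 in the latter alone; exact McNemar test, adjusted p = 1.90e-39). IRF4 72 h peaks did likewise, with 50.2% in the IRF4 48 h list and 28.7% in the IRF8 72 h list (exact McNemar test, adjusted p = 2.20e-24). IRF8 48 h peaks lay in the IRF8 72 h list in 59.0% and in the IRF4 48 h list in 43.6% of cases (exact McNemar test, adjusted p = 1.16e-04). That call ended with lists at full length (difference -6.84 points, exact McNemar test, adjusted p = 0.0671). IRF8 72 h peaks lay in the IRF8 48 h list in 13.0% and in the IRF4 72 h list in 13.3% of cases, with no call at equal length (exact McNemar test, adjusted p = 0.872). At full length the longer IRF4 72 h list held 24.4% of them (exact McNemar test, adjusted p = 9.54e-17). The IRF4 48 h list held 9.07% at equal length, below IRF8 48 h (exact McNemar test, adjusted p = 8.97e-04). At full length it held 26.5%, so this order turned. Erap1, which encodes a peptidase that trims peptides for MHC class I, had the highest single-copy IRF8 peak without IRF4 at the same time. Its promoter peak on chromosome 13, 74777059 to 74777559, held an ISRE and carried 64 tags at 48 h and 143.5 (104 to 193) at 72 h.

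**Figure D3:**
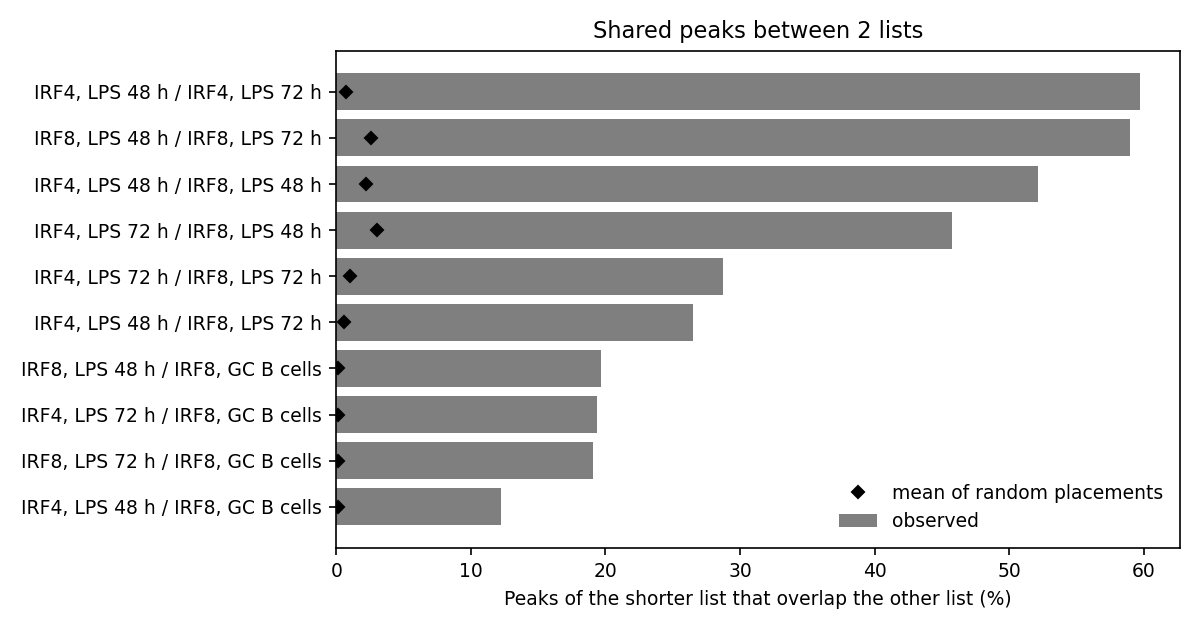
Percentage of peaks of the shorter list that overlap the other list by at least 1 bp (bars, x axis) for all 10 pairs of the 5 lists (y axis), with the mean of 1000 random placements (diamonds). Peaks on unplaced sequences were not moved in these placements, which raises the diamonds of pairs of LPS lists. The pair of IRF4 lists has the longest bar, 59.7%, and the GC list shares 12.3% to 19.7% with an LPS list.

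The third comparison followed IRF8 from 48 h to 72 h. The ISRE share of IRF8 peaks was higher at 72 h, 12% against 5.78% at 48 h (3.11 to 9.68), while the EICE share was 19.6% at 48 h (14.6 to 25.3) and 22.0% at 72 h (19.6 to 24.7). Among single-copy peaks the order of the EICE shares turned, with 25% at 48 h and 24.5% at 72 h. In the top part of the ranked lists the EICE shares were further apart, 17.3% at 48 h and 28.3% at 72 h. Peaks found at 72 h alone held the ISRE in 12.6% of cases and peaks found at 48 h alone in 3.23%. At the 96 single-copy places bound at both times, the median ratio of IRF8 tags at 72 h over 48 h was 1.57 (median log2 ratio 0.65, quartiles 0.36 and 0.90), a value with no test. Pax5 encodes a factor that maintains B cell identity. Its intronic EICE peak on chromosome 4, 44683806 to 44684306, 12.6 kb from a TSS, carried 32.0 normalised IRF8 tags at 48 h (17.5 to 53.7) and 104.4 at 72 h (71.4 to 147).

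The ISRE difference passed Fisher's exact test (odds ratio 48 h over 72 h 0.449, adjusted p = 0.0153; 0.0534 over whole intervals and 0.135 in the top part of the lists). The EICE and AP-1 differences did not pass the Fisher test (adjusted p = 0.528 and 0.206; 0.956 for the EICE with single-copy peaks). The Pax5 ratio of 3.26 passed an exact binomial test (adjusted p = 0.00372 over 87 comparisons of named peaks), a test of these 2 libraries; part of it is the general ratio of 1.57 between them. Of the IRF8 48 h list, 138 peaks (59.0%) lay in the 72 h list (permutation test, adjusted p = 0.001). The 48 h list is the shortest and least enriched, and its ISRE share did not stand above its flanks (3.11%, exact permutation of peak and flank, adjusted p = 0.190) except with windows of 50 bp (4.44%, adjusted p = 0.0128).

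The fourth comparison set IRF8 in GC B cells against IRF8 in LPS cultures. Within 100 bp of the centre the ISRE lay under 13.4% of GC peaks (11.9 to 15.1) and 12% of IRF8 peaks at 72 h of LPS, and the EICE under 7.34% (6.18 to 8.63) and 22.0%. These shares depend on the window, since GC intervals are wider and have no summit. Over whole intervals the ISRE was in 37.3% of GC peaks and 16.3% of 72 h peaks (16.5% and 7.97% in flanks of the same length), and the EICE in 23.0% and 24.8% (13.1% and 4.96% in the flanks). Of the GC peaks, 361 (19.8%, 18.0 to 21.7) lay in any LPS list. At the centres of the 72 h peaks, the 202 places shared with GC B cells held the ISRE in 31.2% and the EICE in 34.7% of cases, and 72 h peaks outside the GC list held them in 7.45% and 19.0%. At the centres of the GC intervals, the shared places held the ISRE in 14.4% and the EICE in 18.8%. GC peaks outside the 72 h list held them in 13.3% and 5.91%. The shared places were not tested against the others, and the shared 72 h peaks had more tags, a median of 39.1 against 29.4. The shared single-copy peaks with the most tags, chosen after the values were seen, included Erap1, the Pax5 intron and a peak in a Bach2 intron (chromosome 4, 32445525 to 32446025, EICE, 68.5 tags at 72 h). Bach2 encodes a repressor that holds back plasma cell differentiation.

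By Fisher's exact test, two-sided, within 100 bp of the centre the EICE passed between IRF8 at 72 h and GC B cells (odds ratio 3.57, adjusted p = 1.12e-27) and the ISRE did not (0.882, adjusted p = 0.376). The ISRE difference, 72 h minus GC, turned to 0.792 points with single-copy peaks and 0.864 with windows of 50 bp, also without a call (Fisher's exact test, adjusted p = 0.639 and 0.565). Over whole intervals, added after the data were seen, the Fisher test passed for the ISRE (0.327, adjusted p = 4.52e-33) and not for the EICE (1.10, adjusted p = 0.383). GC intervals are wider and hold more matches of both elements in their flanks too. Neither whole-interval result can therefore separate a difference in binding from one in width. The 202 shared places were 19.1% of the 72 h list, against 0.130% in random placements (permutation test, one-sided, adjusted p = 0.001). With LPS lists of equal length, GC peaks lay in the IRF8 72 h list in 11.1% and in the IRF4 48 h list in 8.11% of cases (exact McNemar test, adjusted p = 8.97e-04). Against the IRF4 72 h list the shares were 10.5% in the IRF8 72 h list and 9.42% in the IRF4 72 h list (exact McNemar test, adjusted p = 0.276). Against the short IRF8 48 h list, which held 2.52% of GC peaks, the IRF4 72 h list held more, 3.67% (exact McNemar test, adjusted p = 0.0385). This call ended with single-copy peaks (exact McNemar test, difference 1.07 points, adjusted p = 0.0621). At full length the first difference was -0.548 points with no call (McNemar's exact test, adjusted p = 0.561). The GC list shared 46 peaks with the IRF8 48 h list.

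The fixed gene lists showed which genes lay near the peaks. IRF4 peaks at 48 h were near genes of plasma cells, germinal centres, B cell identity, Toll-like receptor and NF-kappaB signalling, and the cell cycle and apoptosis. They lay near 9 of 26 plasma cell genes, among them Prdm1, which drives plasma cell differentiation, and Irf4 itself, near 8 of 25 germinal centre genes and near 9 of 28 B cell identity genes. They also lay near 9 of 30 Toll-like receptor and NF-kappaB genes and near 9 of 23 cell cycle and apoptosis genes, among them Myc and Mdm2. At 72 h IRF4 peaks lay near 6, 5, 8, 5 and 2 genes of these lists. IRF8 peaks at 72 h lay near 7 of 22 antigen presentation genes, among them Cd74, which encodes the MHC class II invariant chain, and Psmb8, an immunoproteasome subunit. In GC B cells IRF8 peaks lay near 12 of these 22, among them Tap1 and Tap2, which carry peptides for MHC class I, and near 12 of 33 interferon response genes, among them Isg15, Ifih1 and Irf7.

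By Fisher's exact test, one-sided, adjusted over the 12 lists of each peak list, IRF4 at 48 h passed for cell cycle and apoptosis (odds ratio 12.8, adjusted p = 7.17e-06), plasma cell (10.5, adjusted p = 1.20e-05) and B cell identity (9.43, adjusted p = 1.62e-05). In the same Fisher test it passed for Toll-like receptor and NF-kappaB (8.53, adjusted p = 2.31e-05), germinal centre (9.36, adjusted p = 3.51e-05) and the AP-1 and BATF family (4 of 17; 6.10, adjusted p = 0.0154). IRF4 at 72 h passed for B cell identity (13.0), plasma cell (9.71), germinal centre (8.08), Toll-like receptor and NF-kappaB (6.46) and the AP-1 and BATF family (3 of 17; 6.90), with adjusted p from 1.46e-05 to 0.0327 in the same Fisher test. Within 10000 bp of a TSS the calls of B cell identity (2.97) and the AP-1 and BATF family (2.41) ended at 48 h (Fisher's exact test, adjusted p = 0.236 and 0.385). At 72 h those of plasma cell (2.48), germinal centre (5.42), B cell identity (4.79) and the AP-1 and BATF family (3.88) ended there (Fisher's exact test, adjusted p = 0.174 to 0.454). The AP-1 and BATF call also ended with every TSS at both times (Fisher's exact test, adjusted p = 0.117 and 0.168), and in the top part of the 72 h list, as did Toll-like receptor and NF-kappaB (4.66, adjusted p = 0.181). Antigen presentation and interferon response did not pass for IRF4 (3 of 22 at each time, Fisher's exact test, adjusted p = 0.143 at 48 h and 0.0552 at 72 h; 3 and 2 of 33, adjusted p = 0.281 and 0.344). Antigen presentation did pass the Fisher test for IRF4 within 10000 bp of a TSS (odds ratio 6.12 at 48 h and 9.86 at 72 h, adjusted p = 0.0469 and 0.0293). With every TSS within 50000 bp it held 11 and 10 of 22 genes (Fisher's exact test, 9.14 and 11.8, adjusted p = 1.32e-05 and 5.75e-06). Cell cycle and apoptosis did not pass at 72 h (Fisher's exact test, odds ratio 3.06, adjusted p = 0.229).

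IRF8 at 72 h passed the same Fisher test for antigen presentation (13.5, adjusted p = 6.34e-05), germinal centre (5 of 25; 7.20), plasma cell (5 of 26; 6.86), and cell cycle and apoptosis (4 of 23; 6.06). It also passed that Fisher test for interferon response (5 of 33; 5.14), B cell identity (4 of 28; 4.80) and Toll-like receptor and NF-kappaB (4 of 30; 4.43, adjusted p = 0.030). Of these, antigen presentation passed in each alternative setting. Within 10000 bp no B cell identity gene had a peak, and plasma cell (4.76), germinal centre (2.37) and Toll-like receptor and NF-kappaB (1.96) did not pass (Fisher's exact test, adjusted p = 0.221 to 0.698). B cell identity also ended with single-copy peaks (3.92, Fisher's exact test, adjusted p = 0.0853), and interferon response (1.77) and Toll-like receptor and NF-kappaB (4.05) in the top part of the list (adjusted p = 0.528 and 0.191). With every TSS, Toll-like receptor and NF-kappaB (1.89) and cell cycle and apoptosis (3.42) ended (Fisher's exact test, adjusted p = 0.265 and 0.0516). The AP-1 and BATF family did not pass for IRF8 at 72 h (2 of 17, Fisher's exact test, adjusted p = 0.166). IRF8 at 48 h passed for 5 lists that held 2 or 3 genes each, germinal centre (17.4, Cd83, Ezh2 and Myc), the AP-1 and BATF family (16.9), antigen presentation (12.7), plasma cell (10.6) and B cell identity (9.74), with adjusted p from 0.0118 to 0.0494 in the Fisher test. Within 10000 bp all of these but antigen presentation had no member with a peak, and in the top part of the list none passed. The plasma cell call ended with single-copy peaks (6.35, Fisher's exact test, adjusted p = 0.282), and the AP-1 and BATF family (7.56) and B cell identity (4.36) ended with every TSS (adjusted p = 0.0830 and 0.170). Interferon response, Toll-like receptor and NF-kappaB, and cell cycle and apoptosis held 1 gene each there. In GC B cells antigen presentation led (19.0, adjusted p = 9.07e-09, Fisher's exact test), with the AP-1 and BATF family (7 of 17; 11), B cell identity (11 of 28; 10.2) and interferon response (9.03). The Fisher test was also passed by germinal centre (8 of 25; 7.42), plasma cell (7 of 26; 5.80), cell cycle and apoptosis (6 of 23; 5.56) and Toll-like receptor and NF-kappaB (5 of 30; 3.14, adjusted p = 0.0470). In GC B cells the calls of plasma cell (3.05) and Toll-like receptor and NF-kappaB (2.60) ended within 10000 bp (Fisher's exact test, adjusted p = 0.153 and 0.186). Both ended with every TSS too, as did cell cycle and apoptosis (Fisher's exact test, adjusted p = 0.0513 to 0.0690).

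Markers of other cell types, immunoglobulin genes and housekeeping genes did not pass the Fisher test by the nearest TSS within 50000 bp in any list, but some passed in other settings. Myeloid and dendritic cell genes had a peak in 1 of 22 cases for IRF4 at 48 h and 2 of 22 in GC B cells, and in none in the other lists. T cell genes had a peak in 2, 2, 0, 1 and 3 of 21 cases in the order of the lists above, immunoglobulin and class switch genes in 2, 1, 0, 1 and 1 of 11, and housekeeping genes in 1, 0, 0, 0 and 1 of 16 (Fisher's exact test, adjusted p of 0.143 or more for each). With every TSS within 50000 bp the myeloid and dendritic cell list passed for IRF4 at 48 h (Fisher's exact test, odds ratio 5.21, adjusted p = 0.00140) and the housekeeping list in GC B cells (7 of 16, odds ratio 4.91, adjusted p = 0.00663). By an exact binomial test over peaks, which rests here on 1 to 3 genes a list, T cell genes passed for IRF4 at 48 h and 72 h and in GC B cells (adjusted p = 0.00915 to 0.0316). Immunoglobulin genes passed the exact binomial test in all lists but IRF8 48 h (adjusted p = 0.0132 to 0.0408). The calls depend on distance: within 10000 bp of a TSS, 5, 2, 1, 3 and 6 lists passed in the order of the lists above, against 6, 5, 5, 7 and 8 within 50000 bp. In the top part of the ranked lists IRF4 72 h kept 3 calls and IRF8 48 h 0, and several antigen presentation genes are neighbours in the MHC region of chromosome 17, so their peaks are not independent.

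Of the genes named in any case, Pax5 had a peak in all 5 lists. Its intronic EICE peak carried 76.5 IRF4 tags at 48 h (50 to 112) and 92.9 at 72 h (64.7 to 129). Bach2 had 6 IRF4 peaks at 48 h, 1 at 72 h, 2 IRF8 peaks at 72 h and 3 in GC B cells within 50 kb of a TSS. The Bach2 intron peak shared by IRF8 at 72 h and GC B cells, named above, lay farther away and is not counted. The IRF4 48 h list was also the longer one. At the only Bach2 place in both IRF4 lists, tags were 58.9 at 48 h and 26.6 at 72 h (exact binomial test, adjusted p = 0.222). Prdm1 had an intronic IRF4 peak with an ISRE at 48 h (chromosome 10, 44164157 to 44164657, 44.2 tags) and a GC peak with an ISRE 1.15 kb upstream of its TSS (44248963 to 44249949). Irf4 had an IRF4 48 h peak with an ISRE 16.4 kb upstream (chromosome 13, 30824492 to 30824992, 53.0 tags) and an EICE peak 20.8 kb upstream in the IRF4 48 h and IRF8 72 h lists (29.4 and 26.1 tags). It also had a GC peak with an ISRE 10.8 kb upstream. Irf8 had a peak 10.8 kb upstream of a TSS, inside an intron of the annotated gene Gm20388, in the IRF4 48 h list (chromosome 8, 123249179 to 123249679, 41.2 tags) and an overlapping one in GC B cells. Zbtb20, a factor of plasma cell survival, had an intronic peak in the 4 LPS lists, and Ebf1, a factor of early B cell development, had intronic peaks in both IRF4 lists and in GC B cells. No peak was assigned to Bcl6, Spib, Ciita or Xbp1 in any list by the nearest TSS within 50 kb.

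A peak in 3 or more lists was found for 32 members of the gene lists. H2-DMb2, which loads peptides on MHC class II, had a promoter peak in all 5 lists (chromosome 17, 34279830 to 34280330 in the IRF4 48 h list). An EICE lay within 100 bp of the centre in the 4 LPS lists. The GC interval (34279494 to 34280410) spans those windows, so it holds the EICE too, outside the window at its middle. Atf3, a stress-induced AP-1 family member, had an EICE peak 14.7 kb upstream in all 5. Cd83, a marker of activated B cells, had peaks 20.1 to 32.6 kb upstream in all 5, but no place common to all. For Cd83 the IRF8 72 h list held only a peak 32.5 kb upstream. The IRF4 72 h and IRF8 48 h lists held only one 23.8 kb upstream. Gbp3, an interferon-induced GTPase, had a promoter peak with EICE, ISRE and AP-1 matches in the IRF4 72 h, IRF8 72 h and GC lists. Ezh2, a histone methyltransferase that GC B cells require, had a peak 26.0 kb upstream (chromosome 6, 47571091 to 47571591) with 100.1 and 100.9 IRF4 tags at 48 h and 72 h, but 29.7 and 52.2 IRF8 tags. The IRF8 48 h value was lower than each IRF4 value (ratios 0.297 and 0.294, exact binomial test, adjusted p = 0.00372 for both). Syk (Sykb in the annotation), a kinase of the B cell receptor, had a peak 10.5 kb upstream with 76.5 IRF4 tags at 48 h and 25.1 IRF8 tags at 48 h (ratio 0.328, exact binomial test, adjusted p = 0.0240). In all, 5 of 87 such comparisons passed; the median single-copy ratio of IRF8 over IRF4 at 48 h was 0.655, so a lower IRF8 value is general to this pair of libraries.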

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

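The tests of list length and of AP-1 against EICE peaks by tags were added after the motif shares were seen and before their own results; the test of EICE peaks against peaks with neither element and the alternatives for the change of the EICE were chosen only after the result was seen. The EICE share of peaks rose more from 48 h to 72 h in the IRF4 lists than in the IRF8 lists. It went from 14.7% to 25.6% for IRF4, a change of 11 percentage points, and from 19.6% to 22.0% for IRF8, a change of 2.49 points. The changes differed by 8.47 points (permutation of the antibody within each culture time, p = 0.00812, adjusted p = 0.0487 over 6 motifs). That permutation takes the 2 factors to be alike at each time, not only in their change, and counts shared peaks as separate. The adjusted p sits at the threshold and does not settle that the changes differ. With autosomes and X only, which leaves out 1 IRF4 48 h window on the mitochondrial chromosome, the difference was 8.46 points (adjusted permutation p = 0.0523). With single-copy peaks the IRF8 change turned to -0.546 points (25% to 24.5%) and the difference was 12.6 points (adjusted permutation p = 0.00258), and with windows of 50 bp 6.80 points (adjusted permutation p = 0.0521). In the top part of each ranked list, where the IRF8 share went from 17.3% to 28.3%, it was 2.93 points (adjusted permutation p = 0.650). For AP-1 the changes differed by -7.14 points (permutation p = 0.0400, adjusted p = 0.103).

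Behind it lies the IRF4 pattern, with a smaller share of AP-1 peaks and a larger share of EICE peaks at 72 h than at 48 h. A longer 48 h list that reaches weaker peaks is argued against by lists of equal length, in which the larger of the Fisher's exact p values for AP-1 and EICE was 6.52e-07, but a larger share of background peaks at 1 of the times had no independent test and stays open for the size of each change, since the odds ratios, 48 h over 72 h, of 1.78 for AP-1 and 0.499 for the EICE are the pattern itself. At places bound at both times the median log2 ratio of tags, 72 h over 48 h, at peaks with AP-1 alone minus that at peaks with an ETS-IRF element alone was -0.42 (also with single-copy peaks), so IRF4 occupancy may have fallen at AP-1 sites, a hypothesis found and tested on the same libraries. EICE peaks minus peaks with neither element was 0.025 (permutation test, two-sided, p = 0.0906) and 0.095 with single-copy peaks (permutation p = 0.0222), so whether tags at ETS-IRF elements rose relative to other places depends on the multi-copy peaks, and their own median fell by 0.27. A difference in immunoprecipitation between the libraries, with 0.82% and 0.45% of tags in peaks and 1 library at each time, stays open.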

How the results depend on the processing

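The tests with single-copy peaks, whole intervals, the exact binomial, autosomes and X for motif and promoter shares, and those for differences in motif share, the change in time, the ISRE share and the IRF4 motifs and tags at 48 h and 72 h were added after the data were seen; of these, equal list length, AP-1 against EICE tags and the ISRE share over whole intervals came before their own results and the others were chosen only after. No paired analysis was possible because each group held 1 library. In 70 alternatives for shared peaks each pair kept its direction and an adjusted permutation p of 0.001. Their shares ran from 4.2% to 17.1% for IRF4 48 h with GC and from 43.2% to 74.4% for IRF8 48 h with 72 h. Motif shares kept direction and side of the threshold in 161 of 174 alternatives. Gene lists did in 216 of 288, differences in shared peaks in 25 of 36 and differences in motif share in 132 of 168. Among the gene lists 27 turned direction, some of them with a call lost or gained as well. Of those that kept direction, 28 lost and 17 gained a call. Promoter shares stayed in their interval in 13 of 19, and the ISRE share among peaks with 1 of both elements kept its call in 4 of 4. Differences in the log2 ratio of IRF4 tags, 72 h over 48 h, kept theirs in 3 of 4, and EICE peaks minus peaks with neither element gained one with single-copy peaks (0.095). The depth of 3065426 to 4375858 tags per LPS library may limit the lists to high peaks, which was not tested. The GC list could not be ranked, so its top part was not run. Unless stated, the cause of a change was not tested.

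With lists at full length the difference in shared peaks, in percentage points, was -10.1 for IRF4 48 h peaks in IRF8 48 h minus IRF8 72 h. For IRF8 72 h peaks it was 11.3 in IRF4 72 h minus IRF8 48 h, and both were newly past the threshold. It lost its call at -6.84 for IRF8 48 h peaks (IRF4 48 h minus IRF8 72 h) and -0.548 for GC peaks (IRF4 48 h minus IRF8 72 h). It turned direction for IRF4 48 h minus IRF4 72 h, at 6.41 for IRF8 48 h peaks, 2.17 for IRF8 72 h peaks and 1.10 for GC peaks. It also turned for IRF4 48 h minus IRF8 48 h, at 13.5 for IRF8 72 h peaks and 8.0 for GC peaks. In each of these 5 the IRF4 48 h list is the longer one by construction. With single-copy peaks it lost its call at -1.92 for IRF4 72 h peaks (IRF8 48 h minus IRF8 72 h) and 1.07 for GC peaks (IRF4 72 h minus IRF8 48 h).

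Among motif shares, windows of 50 bp ended the call of AICE2 (0.256%) and the ISRE (2.37%) for IRF4 48 h and of the ETS site for IRF8 48 h (1.33%). They gave a call to the ISRE for IRF8 48 h (4.44%). Flanks 5000 bp away ended the ISRE call for IRF4 48 h (4.55%) and gave one to AICE2 for IRF4 72 h (0.564%). In the top part of each ranked list the ISRE lost its call for IRF4 48 h (4.36%) and IRF4 72 h (5.22%), as did the ETS site for IRF8 48 h (1.82%). AICE2 gained one there for IRF4 72 h (0.907%) and went to 0% for IRF8 72 h. Whole intervals gave a call to AICE2 for IRF4 72 h (0.790%) and ended that of AICE1 for GC (0.548%). Over whole intervals the difference in motif share, in percentage points, lost its call for IRF4 48 h minus 72 h at 1.55 for AICE1 and -1.42 for the ISRE, for IRF8 48 h minus 72 h at -6.09 for the ISRE and for IRF4 72 h minus IRF8 72 h at 1.95 for the ETS site. The last pair gained one for the EICE (5.10), and IRF4 48 h minus IRF8 48 h turned for the ISRE (0.213). For IRF8 48 h minus GC the EICE (-0.779) and AP-1 (-8.27) turned, AICE2 lost its call (0.560) and the ETS site gained one (-3.75). For IRF8 72 h minus GC AICE2 (-0.138), the ETS site (-2.73) and AP-1 (-12.0) turned, the EICE lost its call (1.81) and the ISRE gained one (-21.0). GC intervals are wider by construction and hold more matches, in the flanks too. With single-copy peaks the EICE gained a call for IRF4 48 h minus IRF8 48 h (-9.80) and turned for IRF8 48 h minus 72 h (0.546). The ETS site lost one for IRF4 72 h minus IRF8 72 h (1.98) and turned for IRF8 48 h minus GC (0.230), where AICE2 lost one (0.568), and the ISRE turned for IRF8 72 h minus GC (0.792). With windows of 50 bp the EICE gained a call for IRF4 48 h minus IRF8 48 h (-6.83) and turned for IRF4 72 h minus IRF8 72 h (-0.036), where AICE1 (0.730) and the ETS site (1.72) lost theirs. For IRF8 48 h minus GC AICE2 (0.444) and the ISRE (-3.66) lost a call and the ETS site turned (0.019), and for IRF8 72 h minus GC the ISRE turned (0.864). In the top part AICE1 lost its call for IRF4 48 h minus 72 h (0.933), IRF4 48 h minus IRF8 48 h (3.20) and IRF4 72 h minus IRF8 72 h (2.21), where the ETS site turned (-0.218). There the ISRE lost its call for IRF4 (-0.851) and IRF8 (-6.96) 48 h minus 72 h, and AICE1 turned for the latter (-0.052). The change of the EICE share in time, IRF4 minus IRF8, lost its call at 8.46 points with autosomes and X, 6.80 with windows of 50 bp and 2.93 in the top part of each list. That of the ETS site turned to -1.87 in the top part.

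Gene list values are odds ratios, and 0 means that no member had a peak. Within 10000 bp calls ended in the IRF4 48 h list for B cell identity (2.97) and AP-1 family (2.41). In the IRF4 72 h list they ended for plasma cell (2.48), germinal centre (5.42), B cell identity (4.79) and AP-1 family (3.88). In the IRF8 72 h list they ended for plasma cell (4.76), germinal centre (2.37) and Toll-like receptor (1.96), and in the GC list for plasma cell (3.05) and Toll-like receptor (2.60). Antigen presentation gained a call for IRF4 48 h (6.12) and IRF4 72 h (9.86). The ratio went to 0 for immunoglobulin in the IRF4 72 h, IRF8 72 h and GC lists. It also did for plasma cell, germinal centre, B cell identity, AP-1 family and cell cycle in the IRF8 48 h list, and for B cell identity and AP-1 family in the IRF8 72 h list. With every TSS within 50000 bp, antigen presentation gained a call for IRF4 48 h (9.14) and IRF4 72 h (11.8) and housekeeping for GC (4.91). Calls ended for the AP-1 family in the IRF4 48 h (2.80), IRF4 72 h (3.03) and IRF8 48 h lists (7.56) and for B cell identity in the IRF8 48 h list (4.36). They ended for Toll-like receptor (1.89) and cell cycle (3.42) in the IRF8 72 h list, and for plasma cell (2.32), Toll-like receptor (2.29) and cell cycle (2.76) in the GC list. The myeloid list turned in the IRF4 48 h (5.21), IRF4 72 h (1.41), IRF8 48 h (2.69), IRF8 72 h (1.23) and GC lists (0.994). So did housekeeping in the IRF4 72 h (3.26) and IRF8 72 h lists (2.84), and immunoglobulin in the GC list (0.629).

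In the top part of each ranked list the ratio went to 0 for immunoglobulin and housekeeping in the IRF4 48 h list, and for the AP-1 family in the IRF4 72 h list. It did so for antigen presentation, interferon response, Toll-like receptor, AP-1 family and cell cycle in the IRF8 48 h list. Calls ended for Toll-like receptor in the IRF4 72 h list (4.66) and for plasma cell (10.3), germinal centre (22.6) and B cell identity (9.53) in the IRF8 48 h list. They ended for interferon response (1.77) and Toll-like receptor (4.05) in the IRF8 72 h list. With single-copy peaks antigen presentation gained a call for IRF4 72 h (5.38). Calls ended for plasma cell in the IRF8 48 h list (6.35) and B cell identity in the IRF8 72 h list (3.92). By the exact binomial test over peaks, whose value is a fold, calls were gained in the IRF4 48 h list for antigen presentation (7.95), interferon response (5.64), immunoglobulin (8.15) and T cell (4.75). In the IRF4 72 h list they were gained for antigen presentation (14), immunoglobulin (14.4) and T cell (8.39). In the IRF8 72 h list they were gained for AP-1 family (6.42) and immunoglobulin (12.2), and in the GC list for immunoglobulin (6.98) and T cell (5.43). The myeloid value of the IRF4 48 h list turned to 1.28. The number of the 12 lists past 0.05 was 10 for IRF4 48 h and 8 for IRF4 72 h with the binomial test. It was 2, 1 and 3 for IRF4 72 h, IRF8 48 h and IRF8 72 h within 10000 bp, and 3 for IRF8 48 h with every TSS. It was 3 for IRF4 72 h and 0 for IRF8 48 h in the top part.

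A promoter of 2500 bp moved the promoter shares to 16.6%, 23.1%, 16.4%, 17.6% and 34.4% in the order IRF4 48 h, IRF4 72 h, IRF8 48 h, IRF8 72 h and GC, as a wider promoter must. The top part moved that of IRF4 72 h to 11.1%. A minimum of 32.6 normalised tags left 969, 350, 79 and 576 peaks in the LPS lists.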

Other observations

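The tests of promoters, repeated sequence and element-bearing shared peaks, and the tests of motifs inside and outside promoters and of gene lists among the ISRE promoters, were chosen only after the result was seen; the test with the whole interval was added after the data were seen and before its own result. Promoter peaks of IRF8 at 72 h of LPS culture were rich in the ISRE. It lay under 33 of 103 promoter peaks, 32.0% (95% interval 23.2 to 42.0), and 9.84% of other peaks (8.02 to 11.9; Fisher's exact test, two-sided, odds ratio 4.32, adjusted p = 2.48e-07). In GC B cells the ISRE lay under 9.75% of promoter peaks and 14.7% of others (Fisher's exact test, adjusted p = 0.0377). The difference between the lists was not tested. GC windows lie at the middle of wide intervals without a summit and can miss an ISRE elsewhere in them. At the 202 places shared by both lists the ISRE was found at 31.2% of the 72 h centres and 14.4% of the GC centres. The 33 genes with an ISRE promoter peak at 72 h and the 46 in GC B cells had 8 in common. These were Aff1, Atad1, Gbp3, Gbp7, Gse1, Mov10, Nmi and Psmb8, named after their values were seen. The genes in GC B cells and those in common may be undercounted for the same reason. Of the fixed lists, antigen presentation held 2 of the 33 genes at 72 h and 2 of 70 other genes with a promoter peak, and interferon response 1 and 3 (Fisher's exact test, two-sided, adjusted p = 0.809 and 1). In GC B cells antigen presentation held 1 of 46 and 8 of 425, and interferon response 4 and 8 (Fisher's exact test, odds ratio 4.96, p = 0.0220, adjusted p = 0.0881 over 4 tests). None of the 4 passed after adjustment, at counts too low to exclude a difference.

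Some genes, also named after their values were seen, had several peaks in a list. The most IRF4 48 h peaks, 6 each, were assigned to Bach2 and to Tg. In GC B cells Elmo1 and Ly6e had the most IRF8 peaks, 5 each, and Cd83 and Lrch1 had 4 each. Bach2 also had 3 in GC B cells, and Elmo1 3 for IRF4 at 48 h.

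The peaks with the most tags lay at the same places in the 4 LPS lists. Of the 20 highest peaks, at least 80% in each list were multi-copy or unplaced, against 4.06%, 5.58%, 19.2% and 12.1% of the others, so reads of repeated sequence piled up on few mapped copies are a candidate source. The multi-copy peaks found in all 4 lists rarely held an EICE or ISRE. The share was 0% to 4%, against 33.3% to 40% of single-copy ones, with a largest Fisher's exact p of 0.00175 over the 4 lists. This cannot decide whether IRF4 or IRF8 bound there. Multi-copy peaks can be copies of the same sequence and so are not independent, AP-1 sites were not counted, and most single-copy peaks lacked both elements too. The single-copy peaks near Axin2, Cdk8 and Pak3 are not covered by these shares and stay open as well.

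Among peaks with 1 of both elements, EICE or ISRE, the ISRE made up 69.5% in GC B cells (198 of 285, 63.8 to 74.8) and 33.4% for IRF8 at 72 h of LPS (106 of 317; Fisher's exact test, odds ratio 4.53, p = 5.81e-19). Over the whole interval the shares were 67.8% against 37.6%. This cannot decide whether wide GC intervals whose centre misses the site play a part. Wide intervals hold more matches by chance, and the GC flanks held the ISRE more often than the EICE (3.07% and 2.03% in windows of the usual size). More promoter peaks are argued against by peaks over 1000 bp from a TSS, with 68.5% against 29.5%, and repeated sequence by single-copy peaks, with 65.2% against 30.9%. The caller and the handling of the cells differ along with the cell type, so whether the GC state has a part in this stays open and was not tested.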
